A study of Mus musculus with 5 samples.

How the data were processed

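The series holds 5 mouse libraries from pro-B cells, an early stage of B-lymphocyte development. Per the labels' protocols, fetal liver cells that lack Ebf1 were transduced with wild-type EBF1 or with an EBF1 form called YmA. EBF1 is a transcription factor needed for B-cell development. Chromatin was crosslinked with formaldehyde, sheared by sonication and precipitated with an antibody against EBF1 or against BRG1, the ATPase of the BAF chromatin remodelling complex. Each group holds 1 library, so nothing here has a replicate. The groups are the input for the EBF1 ChIP, EBF1 ChIP with wild-type EBF1, EBF1 ChIP with YmA, the input for the BRG1 ChIP, and BRG1 ChIP with YmA.

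Of these 5, 1 entered with a processed file, the EBF1 ChIP with wild-type EBF1. The YmA, BRG1 and input libraries were not analysed here, so no occupancy was compared between libraries. The deposited file is a list of site positions with a text class for each site, in units of bp on the chromosome. It gives no score, height, fold or p-value per site, so the strength of a site and the read depth behind it are unknown. Per the submitters' processing notes, the authors used Bowtie2, SAMtools and deepTools with GRCm38 (mm10). The peak caller, its threshold and the step that gave all sites a width of 300 bp are not given in the sources used here. The class column is named, per the file headers, as a deepTools group and holds YmA-dep, YmA-ind and CTD-ind. How the authors assigned sites to these classes, and what the abbreviations stand for, is not given in the sources used here.

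Gene positions came from a RefSeq gene table of the same build, GRCm38. It listed genes of unplaced and alternate scaffolds under their chromosome, and 345 of these were left out, which kept 49209 genes, 21521 of them protein-coding. The table gives no strand and no exons, and no genome sequence was used here. A promoter could therefore not be told from the other end of a gene. The share of sites within 1 kb of either end of a gene took the place of the planned promoter share, and the share inside a gene took the place of exon and intron. The EBF motif, other motifs and peak strength, all planned, were not run.

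Each site was represented by its centre. It was assigned to the shortest protein-coding gene that held it, or otherwise to the nearest within 100 kb. Positions are 1-based. Location and clusters were compared with 1000 random placements of the sites on the same chromosomes, between the outermost protein-coding genes, with two-sided empirical p-values. A cluster was 3 or more sites with gaps under 12.5 kb. For 12 gene lists (211 genes, all matched by symbol or synonym), the number of genes with a site was compared with 10000 random lists of the same size. Random lists were matched on 10 bins of the length of chromosome assigned to each gene, which permutes list membership among genes within a bin. These p-values were adjusted by the Benjamini-Hochberg method over the 12 lists, or over 36 tests where lists were tested by class. The smallest p-values possible were 0.002 for placements and 0.0002 for lists.

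By the plan, sites were to be assigned to the gene with the nearest start, and random placements were to avoid unsequenced stretches. Without strand and sequence, gene spans took the place of starts in the assignment and the matching. Random placements could fall in unsequenced stretches. The lists, the distances, the numbers of random draws and the rule for named genes were fixed before the data were examined. The rule took list members with a site for the B-lineage, T and myeloid lists, up to 5 members with the most sites for other lists, and the 10 genes with the most sites. B-lineage list members without a site are also named, which was decided after their values were seen. The site of 1 list member is not reported here by name. The class column was unknown before, so comparisons between classes were chosen after the list was seen. They used two-sided Fisher's exact tests, adjusted over 9 contrasts, and all 7493 rotations of the class labels along the sorted sites, which keep the order of neighbouring labels. Families by gene symbol, receptor loci, neighbour classes and chromosome relations were also chosen after the list was seen. Neighbour classes were tested with 10000 permutations of the labels. Intervals of shares are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. Sites are not replicates, so every p-value describes this list and not the spread between cultures.

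The tests were checked on 20 simulated site lists without and 20 with planted effects. Simulated sites were placed at random on the same chromosomes with shuffled classes. The check therefore does not cover sites that are grouped along the genome or follow genes. It used fewer random draws than the tests, and the class contrast was called on an unadjusted p-value. Without effects, 0 list calls were made over 21521 genes, the class contrast near gene ends was called in 0 of 20 and the neighbour test in 1 of 20 over 7494 sites. With sites planted at 75% of the genes of 4 lists, 98.8% of the planted lists were called and 0% of the others. With 20% of CTD-ind sites moved to gene ends, the contrast of CTD-ind with YmA-dep was called in 20 of 20 simulations. With 20% of neighbours given the class of the site before, the neighbour test was called in 20 of 20.

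Alternatives covered the distance that counts as near, protein-coding genes only, the assignment rule, an unmatched Fisher's exact test and the cluster gap. Added after the data were seen were 1 site per run of neighbours, the class rotations, and lists without X or without the Igk locus. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.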

Results

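The site list given with the ChIP-seq of EBF1 in pro-B cells carrying wild-type EBF1, 1 library, held 7494 sites on 20 chromosomes, each 300 bp wide. Whether the list holds all sites of that library, or a selection made with other libraries, is not given in the sources used here. The series title places the experiment in a study of phase separation and the pioneering function of EBF1, the binding of a factor to closed chromatin. The authors had put each site in 1 of 3 classes. YmA-ind was the largest with 4055 sites (54.1%, 95% interval 53.0 to 55.2%). CTD-ind held 2550 (34.0%, 33.0 to 35.1%) and YmA-dep 889 (11.9%, 11.1 to 12.6%). The step that made the classes is not given in the sources used here, so their names are used as labels only. Of all sites, 7082 were assigned to a protein-coding gene, and 4213 of 21521 such genes (19.6%) had at least 1 site.

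Which genes carried EBF1 sites was asked first. Genes of the B lineage carried sites far more often than matched genes, while lists of other lineages did not pass the test. Of 22 genes of pre-B-cell and B-cell receptor signalling, 18 had a site, against 4.24 in matched random lists. Of 20 B-lineage transcription factor genes, 19 had a site, against 5.38. The list of IL-7 and PI3K signalling and survival genes had sites at 13 of 17 members, against 3.55, and the list of recombination and early B surface genes at 11 of 17, against 3.38. The adjusted p was 0.0006 for each of these 4 lists, from p = 0.0002, the smallest that 10000 random lists can give (permutation of list membership).

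**Figure D1:**
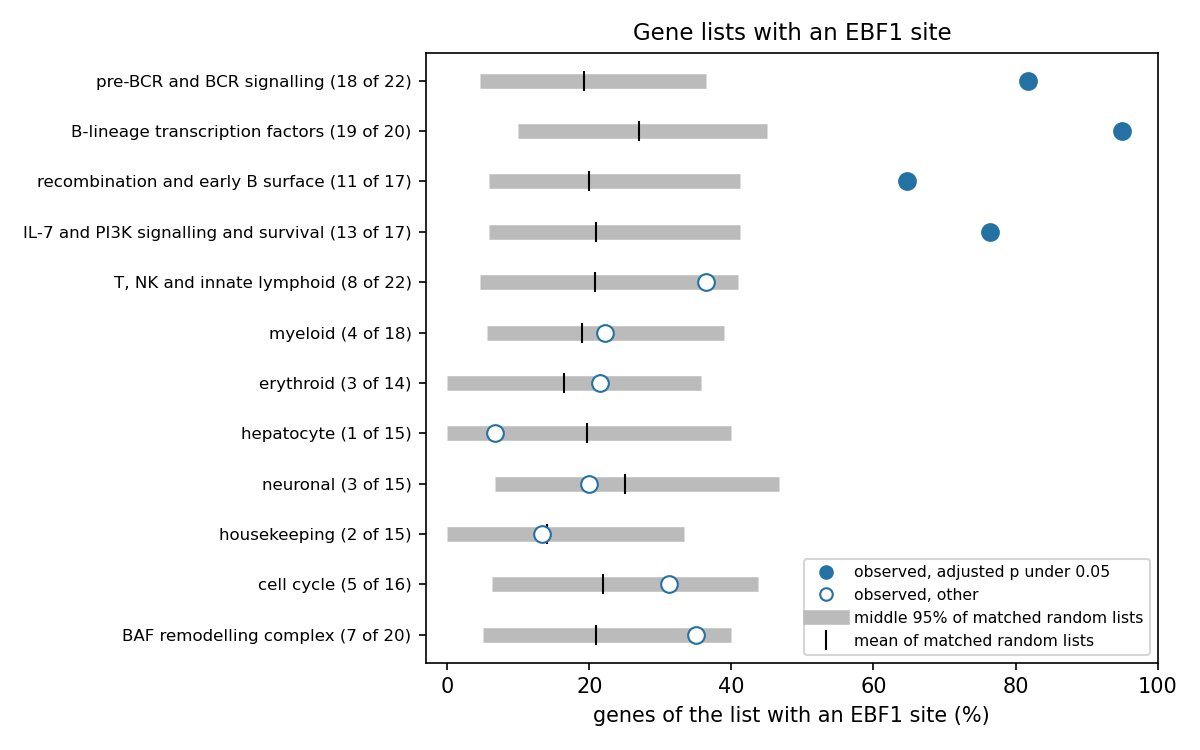
Percent of the genes of each list with an EBF1 site (points), the mean of 10000 matched random lists (ticks) and the middle 95% of those lists (grey bars). Filled points, with adjusted p under 0.05, are the 4 B-lineage lists, from 64.7% (recombination and early B surface) to 95% (B-lineage transcription factors), and the other 8 lists lie within the grey bars.

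In the receptor signalling list, sites sat at the ends of genes for the pre-B-cell receptor and its signalling chains. At Cd79a, which encodes the signalling chain Ig-alpha, a CTD-ind site on chromosome 7 (24897194 to 24897493) was centred 153 bp outside the gene. At Cd79b, the gene of its partner Ig-beta, a CTD-ind site on chromosome 11 (106314471 to 106314770) was centred 59 bp outside. The surrogate light chain genes Igll1 and Vpreb1 on chromosome 16 had CTD-ind sites at 188 bp (16864023 to 16864322) and 122 bp (16869227 to 16869526), and Vpreb3 on chromosome 10 had one at 107 bp (75949614 to 75949913). Vpreb1 has a close paralog, Vpreb2, which had 3 sites, so the placing of reads between these genes is uncertain. Cd22 had a CTD-ind site inside the gene, 1.27 kb from its end. The adaptor gene Blnk had 4 sites, Plcg2 had 5, Bank1 had 4, and the kinase gene Blk had 2, both YmA-ind. Inside the gene or within 10 kb lay 2 sites at Blnk and 1 at Blk. Syk, Fcrl1, Fcgr2b and Cd38 had none.

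Among the B-lineage transcription factor genes, Foxo1 had the most sites, 10, of which 7 were YmA-ind and 3 CTD-ind. A CTD-ind site on chromosome 3 (52268114 to 52268413) was centred 73 bp outside Foxo1, and 4 of the 10 lay inside the gene or within 10 kb of it. Pax5, which maintains B-cell identity, had 4 sites, all inside the gene on chromosome 4, with 2 CTD-ind and 2 YmA-ind. Irf8 had 6 sites (3 CTD-ind, 3 YmA-ind), of which 2 remained when only sites inside the gene or within 10 kb counted. Lef1 had 6 and Ikzf3 had 4, all YmA-ind, and 3 sites lay inside Lef1 or within 10 kb of it. Erg had 5, of which 2 were YmA-dep. Pou2af1 had a CTD-ind site 459 bp outside on chromosome 9 (51213081 to 51213380), and Spib had a YmA-ind site at 354 bp. Ikzf1 was the only member of this list without a site.

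**Figure D2:**
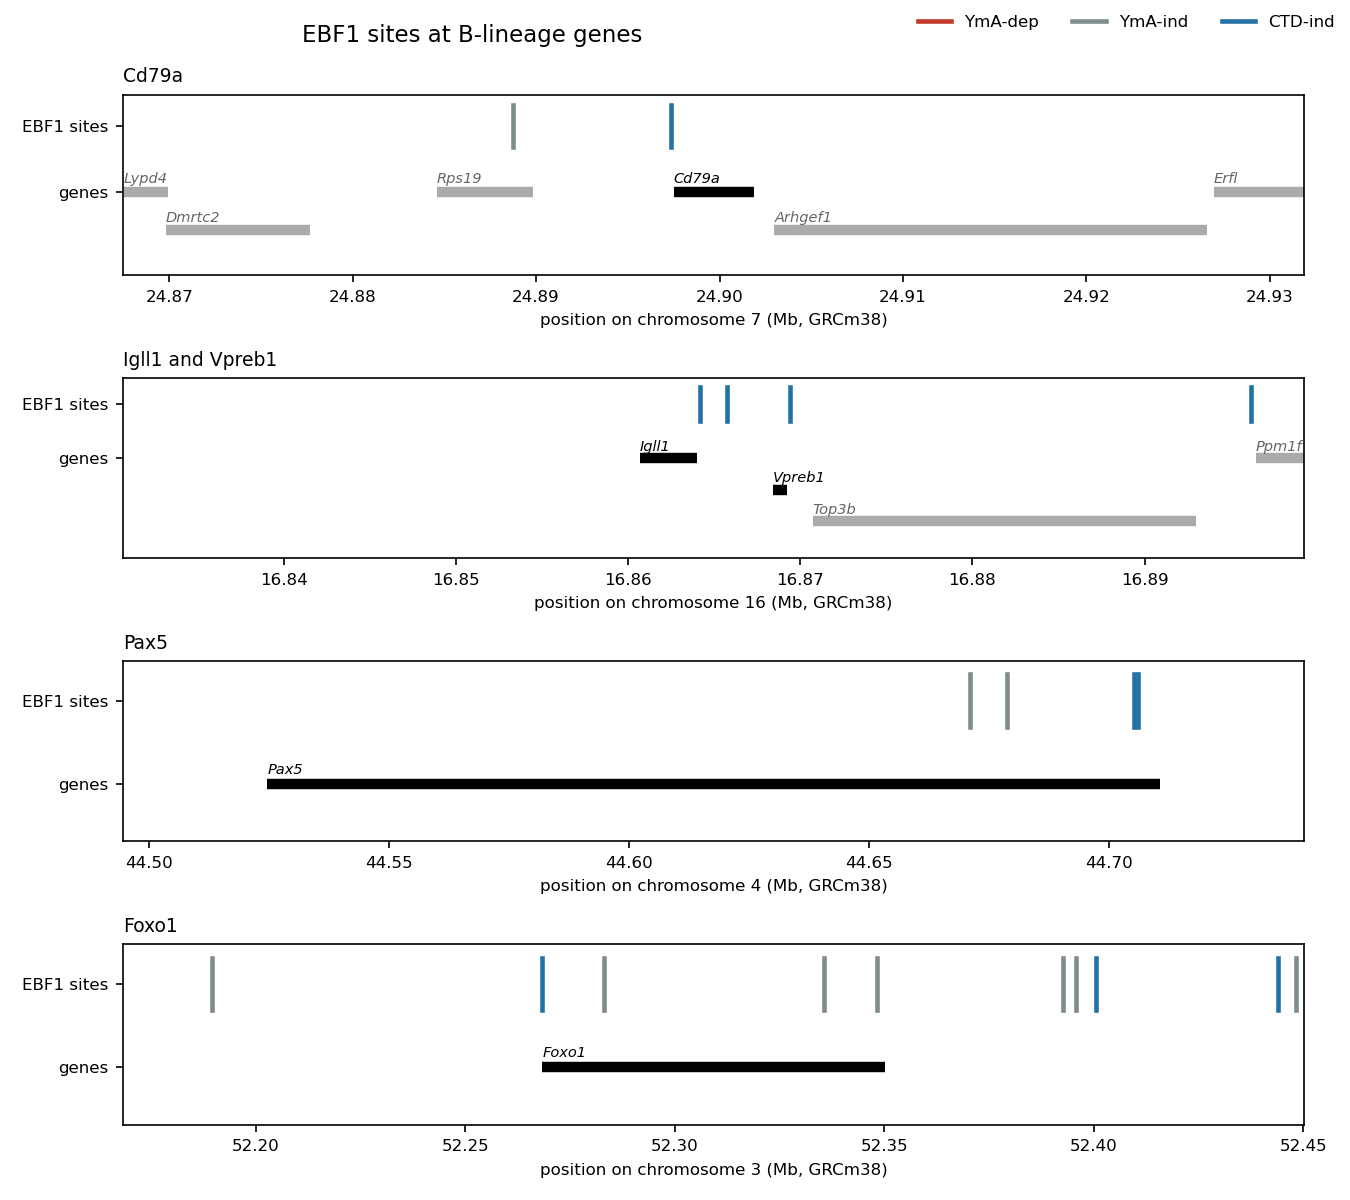
EBF1 sites (vertical lines, coloured by class) and protein-coding genes (bars) at Cd79a, Igll1 with Vpreb1, Pax5 and Foxo1, by position in Mb on GRCm38; line width is not to scale. CTD-ind sites lie at the end of Cd79a (153 bp), Igll1 (188 bp), Vpreb1 (122 bp) and Foxo1 (73 bp), and the 4 Pax5 sites lie inside the gene.

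In the surface and recombination list, CTD-ind sites were centred outside Cd37 (52 bp), Cd40 (340 bp) and Ceacam1 (214 bp). A YmA-dep site lay 55 bp outside Cxcr5 on chromosome 9 (44526349 to 44526648). The recombination genes Rag1, Rag2 and Dntt and the receptor gene Il7r had no assigned site, and neither did Cd53 and Ly6d. A site assigned to another gene lay within 10 kb of Rag2. In the IL-7 and PI3K list, Stat5b had 6 sites, Pik3cd, Bcl2l1 and Inpp5d had 5 each, and Il2rg had a CTD-ind site at 70 bp on chromosome X (101268175 to 101268474). Jak1, Jak3 and Akt1 had none. Stat5a, which adjoins Stat5b, was assigned none, but 3 sites lay inside it or within 10 kb.

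Under the main assignment, lists of other lineages and functions stood within the range of matched lists. The T, NK and innate lymphoid list had sites at 8 of 22 genes, against 4.56 (adjusted permutation p = 0.334). With sites inside a gene or within 10 kb it had 10 of 22, against 5.09 (permutation p = 0.034, adjusted p = 0.068). Within 20 kb it had 8, against 3.80 (permutation p = 0.044, adjusted p = 0.107). An excess in this list was thus not called but is not excluded. Its members with the most sites were Notch1 (7), Tcf7 (5) and Id2 (4, of which 1 lay within 20 kb). The myeloid list had 4 of 18, against 3.42 (adjusted permutation p = 1), with 5 sites at Cebpb, 1 of them inside the gene or within 10 kb, and 3 at Itgam. The hepatocyte list had 1 of 15 (Ahsg, against 2.95) and the erythroid list 3 of 14, among them Gfi1b with 3 sites (against 2.30). Neuronal genes had 3 of 15 (against 3.75), housekeeping genes 2 of 15 (against 2.11) and cell cycle genes 5 of 16 (against 3.50). For these lists the adjusted p was 0.589 or higher. The BAF complex list had 7 of 20, against 4.19 (adjusted permutation p = 0.4), with 7 sites at Arid1b. With sites inside a gene or within 10 kb, this became 11 of 20 (adjusted permutation p = 0.035).

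Where the classes lay relative to genes was asked next. CTD-ind sites lay at gene ends most often: 34.9% (33.0 to 36.7%) were within 1 kb of an end of an annotated gene, 5.25 times the random placements. YmA-ind sites followed with 15.3% (14.2 to 16.4%, 2.33 times) and YmA-dep sites with 11.1% (9.14 to 13.4%, 1.70 times). Each class stood above random placement (adjusted p = 0.002, the smallest possible; n = 889 sites in the smallest class). Without the sites in the immunoglobulin kappa (Igk) locus, YmA-dep sites were at 9.53% (1.465 times), YmA-ind sites at 15.0% and CTD-ind sites at 34.9%. With protein-coding genes only, CTD-ind sites were at 28.9% (8.69 times) and YmA-ind sites at 9.82% (3.01 times). YmA-dep sites were then at 3.82%, against 3.28% in random placements (adjusted p = 0.394, n = 889 sites), so their excess did not hold there. The median distance to the nearest end of a protein-coding gene was 5.56 kb for CTD-ind, 14.2 kb for YmA-ind and 18.7 kb for YmA-dep sites.

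**Figure D3:**
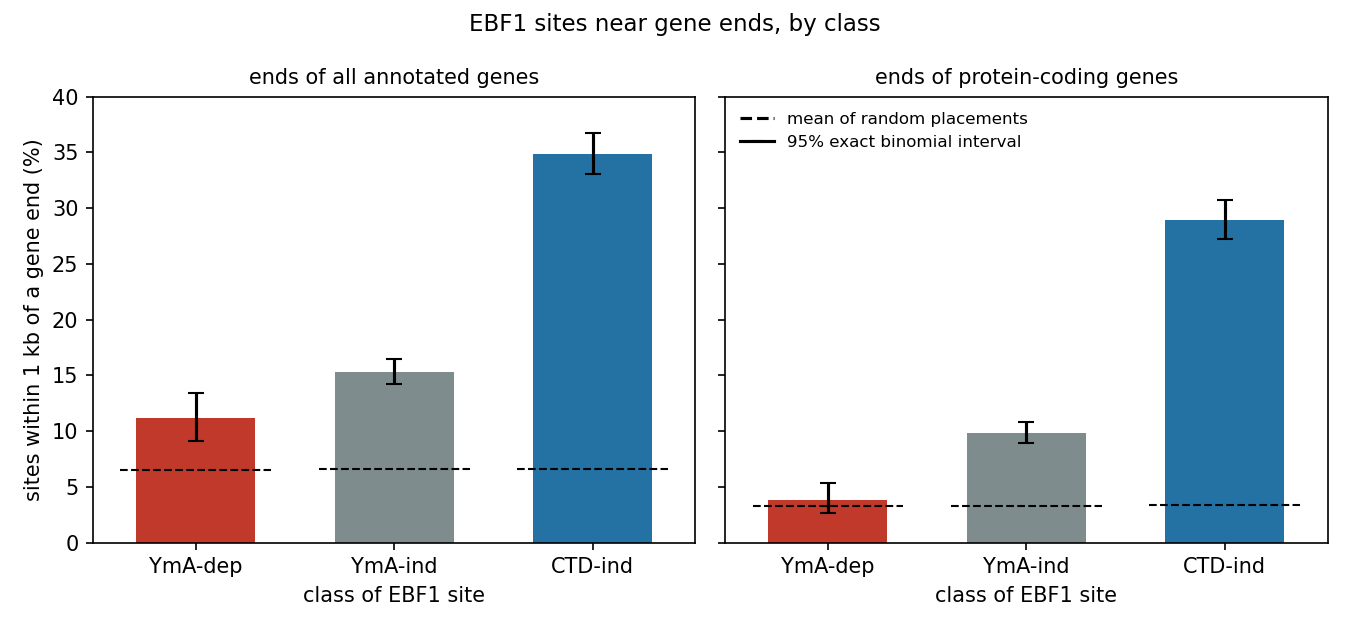
Percent of the sites of each class within 1 kb of a gene end (bars, from 0) with exact 95% binomial intervals, beside the mean of 1000 random placements (dashed lines), for all annotated genes (left) and protein-coding genes (right). CTD-ind sites stand highest in both panels, at 34.9% and 28.9%, and YmA-dep sites lowest, at 11.1% and 3.82%.

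The differences between classes were tested directly. CTD-ind exceeded YmA-dep sites near gene ends by 23.7 percentage points (odds ratio 4.27, Fisher's exact test, adjusted p = 8.11e-46) and YmA-ind sites by 19.6 points (odds ratio 2.97, adjusted p = 2.65e-73). Rotating the class labels along the genome gave p = 0.000133 for both, the smallest possible (rotation permutation, adjusted p = 0.0006). YmA-ind exceeded YmA-dep sites by 4.15 points (odds ratio 1.44, Fisher's exact test, adjusted p = 0.00399). This smaller difference was no longer called when near meant 2.5 kb (3.04 points, exact test, adjusted p = 0.122). Sites inside genes made up 67.4% of YmA-dep, 65.6% of YmA-ind and 66.3% of CTD-ind sites, and no pair of classes differed by the test (adjusted p of 0.399 or higher). All 3 shares stood above random placement, which gave 50.0% over all sites (adjusted p = 0.002, the smallest possible, n = 7494 sites).

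B-lineage genes carried sites of each class, and the class make-up at these genes did not differ from that at matched genes by the test. CTD-ind sites were found at 14 of 22 receptor signalling genes (against 2.04 in matched lists), 14 of 20 transcription factor genes (2.44), 11 of 17 IL-7 and PI3K genes (1.65) and 8 of 17 surface and recombination genes (1.60), each with adjusted permutation p = 0.0012. YmA-ind sites were found at 8, 13, 9 and 7 genes of these lists (adjusted p of 0.0207 or lower). YmA-dep sites passed the test in the receptor signalling list only, at Lyn, Cd72, Blnk and Bank1, 4 of 22 genes against 0.689 (adjusted permutation p = 0.0336). That call was lost with no distance limit (adjusted permutation p = 0.0528) and with a limit of 20 kb (0.0576). The 20 kb limit also ended the YmA-ind calls of the receptor signalling list (0.0576) and the surface and recombination list (0.152), and the CTD-ind call of the latter (0.0736). Among the 36 sites at receptor signalling genes, 18 (50%) were CTD-ind, against 34.0% at genes with as many sites (adjusted permutation p = 1).

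EBF1 sites were grouped along the genome. With gaps under 12.5 kb, 1154 sites (15.4%) fell into 327 clusters of 3 or more, against a mean of 13.3 and a maximum of 25 clusters in random placements (p = 0.002, the smallest possible, n = 7494 sites). The largest cluster held 12 sites on chromosome 5 (136625642 to 136703076) from the space between Cux1 and Myl10 across Myl10. Clusters of 9 sites lay at Cyth1 on chromosome 11 (118179889 to 118223998) and at Pde2a on chromosome 7 (101456858 to 101483820). CTD-ind sites were in a cluster in 16.7% of cases and YmA-dep sites in 12.7% (difference 4.00 points, Fisher's exact test, adjusted p = 0.0101). That difference lost its call with gaps under 25 kb (3.76 points, exact test, adjusted p = 0.0675). The number of clusters was 129 with gaps under 5 kb (2.44 in random placements) and 560 with gaps under 25 kb (47.5). Random placements did not follow genes as the sites did. How much of the excess of clusters comes from sites lying at genes was not tested.

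The 10 genes with the most sites spanned 13.0 kb (Myl10) to 404 kb (Hivep3). Cux1 and Zmiz1 had 13 sites each, Cyth1, Med13l and Myl10 had 12, Cmip, Hivep3 and Pde2a had 11, and Arhgef3 and Foxo1 had 10. All 11 sites of Hivep3 and of Pde2a and all 10 of Arhgef3 lay inside the gene, while 2 of the 12 at Myl10 did. Cux1 had 9 CTD-ind and 4 YmA-ind sites, and Arhgef3 had 8 YmA-ind sites among its 10. The ranking rested on the 100 kb assignment limit. With sites inside the gene or within 10 kb, Cux1 and Med13l had 7 each and Myl10 and Foxo1 had 4 each, and with no limit Zmiz1 had 21. Of the genes with sites, 2754 had 1 site and 187 had 5 or more.

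The Ebf1 locus was examined because the cells lacked Ebf1 and received it by transduction. Within 100 kb of Ebf1 on chromosome 11 (44618100 to 45008096) lay 7 sites, 3 of them inside the gene. Inside were a CTD-ind site (44893150 to 44893449) and YmA-ind sites at 44911357 to 44911656 and 45002027 to 45002326. A YmA-ind site (45008102 to 45008401) was centred 0.156 kb outside the gene. Exons were not separable here, so overlap with the transduced coding sequence was not tested.

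The antigen receptor loci, examined after the list was seen, differed in their sites. The Igk locus, which holds the immunoglobulin kappa light chain segments, had 57 sites on chromosome 6 (67555636 to 70723923), 6.46 times the number at the density of that chromosome (8.82). Of these, 29 were YmA-dep (50.9%, 37.3 to 64.4%), against 11.6% of sites elsewhere (odds ratio 7.92, Fisher's exact test, p = 5.20e-13). Another 24 were YmA-ind and 4 were CTD-ind. The Igh heavy chain locus on chromosome 12 had 14 sites (6.34 at the density of the chromosome), of which 11 were YmA-ind, 3 CTD-ind and 0 YmA-dep. The Tra and Trd loci had 7 sites, Trb had 4, Igl had 1 and Trg had 0, and of these 1 site, in Trb, was YmA-dep.

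**Figure D4:**
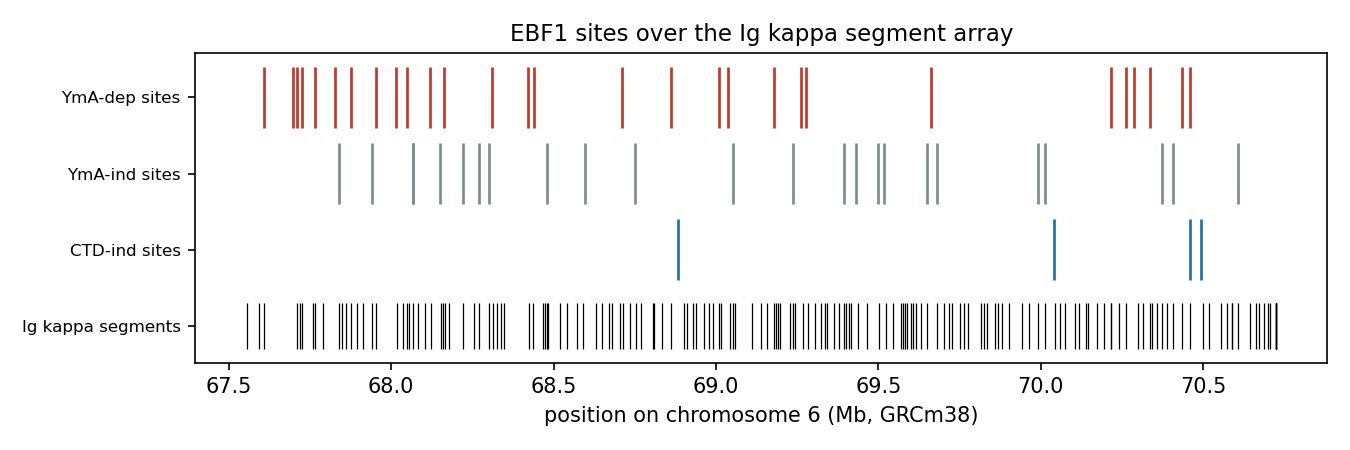
Positions of EBF1 sites over the Igk locus on chromosome 6 (Mb, GRCm38), in 1 row per class, above the 167 annotated kappa segments (black lines). The 29 YmA-dep and 24 YmA-ind sites are spread over the locus, and 4 sites are CTD-ind.

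Sites followed gene density from chromosome to chromosome, and X had few sites for its genes. Over the 20 chromosomes, sites per Mb rose with protein-coding genes per Mb (Pearson r = 0.83, Spearman rho = 0.91, permutation p = 1e-05 for each, the smallest possible, adjusted p = 2e-05). Without the 2 chromosomes farthest from the median gene density, r was 0.86. X, the lowest in both densities (5.75 genes and 0.459 sites per Mb), was included each time, and the relation without X was not computed. X had 77 sites, 8.00 per 100 protein-coding genes, against 36.1 over the autosomes and 25.9 on the lowest autosome, chromosome 7. Among the X sites were those at Btk and Il2rg, both CTD-ind. The CTD-ind share of a chromosome's sites was not related to gene density by the test (r = 0.44, rho = 0.43, permutation p = 0.0507 and 0.0586, adjusted p = 0.0782), and r was 0.14 without the 2 farthest chromosomes. These were the 2 relations computed, each as r and rho with and without those chromosomes.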

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

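Alternatives without X, without the Igk locus, with 1 site per run of neighbours and with rotated class labels were chosen after the data were seen. Over 137 reported values, 394 of 432 alternative values kept their direction and side of the threshold or stayed within their interval, 3 were weaker, 1 stronger, 8 reversed and 26 moved. Most of the 432, 309, were counts of sites per named gene. Their intervals were wide at low counts, so that Mycn stayed within its interval with 1 site and with 5 (no distance limit). The total therefore says little about how firm the main results are. The main class result, CTD-ind sites near gene ends against each other class, was kept in all alternatives run. With protein-coding genes only, YmA-dep sites near gene ends fell to 3.82% and were no longer above random placement. YmA-ind minus YmA-dep near gene ends fell to 3.04 points when near meant 2.5 kb, and CTD-ind minus YmA-dep in clusters to 3.76 points with gaps under 25 kb, and for these 3 the cause was not tested.

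Reversed values belonged to differences that had not passed a test. For sites inside genes, CTD-ind minus YmA-dep became 3.13 points with protein-coding genes only and 0.305 points with 1 site per run, and YmA-ind minus YmA-dep became 1.28 points with protein-coding genes only. Lists that crossed the mean of matched lists were the myeloid list (3 genes with the 10 kb flank, 2 within 20 kb), neuronal (3, unmatched Fisher's exact test), housekeeping (2, within 20 kb) and cell cycle (2, 10 kb flank), and the cause was not tested. The 4 B-lineage lists were called under each assignment, and the 10 kb flank called 5 lists. By class, the lists called for YmA-dep sites went from 1 to 0 with no distance limit and within 20 kb, and within 20 kb those for YmA-ind sites went from 4 to 2 and those for CTD-ind sites from 4 to 3. Clusters numbered 129, 327 and 560 with gaps under 5, 12.5 and 25 kb. Of 309 counts of sites per named gene, 23 moved beyond their interval, for example at Cxcr4 (4 sites, 0 within 20 kb).

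Planned but not run, for want of a score, unequal widths, a sequence, exons or another list, were the motif analyses with their alternatives, peak strength, stricter peak thresholds, repeats and shared peaks. Read depth is unknown, so a gene without a site cannot be read as unbound.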

Other observations

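The tests of neighbouring classes by distance and by region, and of other receptor loci, were chosen after the result was seen. Gene families defined by symbol, also chosen after the data were seen, showed where sites were scarce. Of 59 families of 30 or more genes, 3 had more genes with a site than matched lists and 9 had fewer (adjusted p under 0.05). The families above were the Sh family of SH2 and SH3 adaptor genes (19 of 38 genes, against 8.30), Ppp phosphatase genes (26 of 77, against 15.3) and Tbc genes (14 of 30, against 6.86). Below were Vmn vomeronasal receptor genes (5 of 352, against 71.0), Tex genes (1 of 39, against 7.61) and the Scgb, Pramel, Defb, Krtap, Tas and Rhox families, each with 0 genes with a site. Rhox genes lie on X, where sites were few. Random lists drew genes singly, so the p-values treat family members that lie side by side as independent. Reads shared between like genes were not examined, so a family with few sites cannot be read as unbound.

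EBF proteins are also known as olfactory factors, so a hypothesis was that EBF1 also binds olfactory receptor genes in these cells. Of 1109 Olfr genes, 7 had a site, against 164 in matched lists (range of the middle 95% 143 to 186). The permutation p was 0.0002, the smallest possible, which goes against an excess of called sites at these genes. Random lists drew genes singly, so this p-value treats neighbouring genes as independent. Read depth is unknown and reads shared between like genes were not examined, so binding at these genes is not excluded. Matching covered the length of chromosome assigned to a gene and not its chromatin, which was not measured here.

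CTD-ind sites lay near gene ends more often than YmA-dep sites by 23.7 points. Gene-dense neighbourhoods could give this, but after moving each site by 20 kb to a random side only 6.58% of the difference was left (95% range -5.84 to 18.2%). Different chromosomes could too, but equal chromosome weights kept 103% of it (100 to 107%). What stays open is how the authors cut the classes and how tall the sites were: a tall site may be less likely to be called dependent, and no height was analysed here. No biological explanation was tested, since the YmA library was not analysed here.

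YmA-dep sites made up 29 of 57 sites in the Igk locus. The stretch of 57 consecutive sites on a chromosome with the most YmA-dep sites held 30. With the Igk sites not counted, no such stretch held more than 19. Labels permuted within chromosomes gave at most 22 in 1000 permutations (permutation p = 0.001 for the 30, the smallest possible). These permutations did not keep the order of neighbouring labels. Receptor segment arrays in general do not account for it, since 1 of the 26 sites in the other arrays (3.85%, upper 95% bound 19.6%) was YmA-dep, below the lower bound of 37.3% in Igk. Reads shared between like V segments stay open, since no sequence was used here and 17 of the 29 YmA-dep and 16 of the 28 other Igk sites lay within 1 kb of a segment end. Sites farther away can lie in repeated stretches too, since 5 of those 24 sites lay 1.07 to 1.21 kb beyond the same side of an Igkv13 segment in genome coordinates, and a difference in binding of the YmA form was not tested.

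Neighbouring sites under 12.5 kb apart were of 1 class in 46.6% of 1660 pairs, against 42.4% with labels permuted within chromosomes (permutation p = 0.001). Nearness to gene ends could give this, but permuting among sites at like distance gave 43.2% (permutation p = 0.005). Regional class make-up could too, but permuting within 1 Mb windows gave 43.7% (permutation p = 0.0134). Class make-up of regions smaller than 1 Mb, and distance and region together, were not tested. Outside the Igk locus the share was 46.6% over 1653 pairs, against 42.5% with permuted labels (permutation p = 0.0008). Shared reads or signal between sites that lie close together stay open.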
